A study of Homo sapiens with 6 samples.

How the data were processed

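The series measured total RNA from WPMY-1 cells, an immortalised line of human normal prostate stromal cells, with 3 libraries from cells carrying the empty pLKO1 vector (shCtrl) and 3 from cells carrying a short hairpin RNA against CAVIN1 (shCAVIN1). Per the labels' protocols, the lentiviral constructs were packaged in HEK293T cells, transduced cells were selected with puromycin into stable knockdown clones, RNA was extracted with TRIzol, and libraries were made with an Illumina stranded kit for total RNA. The labels call the 3 libraries of each group independent biological replicates, but they do not say whether these came from separate transductions or clones, so the p-values measure the spread between these libraries.

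The authors deposited a single table of FPKM values (fragments per kilobase of transcript, scaled by the mapped fragments of the library) with 33117 gene symbols and 1 column per library. Per the submitters' processing notes, the genome build was GRCh38 and the tools included CASAVA, bcl2fastq 2.17.1.14, TopHat2 (version given as 2.2.5) and TopHat. The quantifier, the gene annotation, the filters and the strand setting are not given in the sources used here. The deposited FPKM values divide by transcript length and by the number of mapped fragments, so a few very abundant RNAs in a library lower the values of all its other genes. The 10 most abundant rows held between 21.1% and 42.5% of the FPKM sum of a library, and the sums lay between 758837 and 1043843. Protein-coding genes alone summed to between 476434 and 525734. Whole fragments were not recovered from the values, so no count model was used. The absolute depth is unknown. The most common ratio between the lowest values of a gene (FPKM under 0.02) in a library and in shCtrl replicate 2 gave relative depths of 1.2, 1 and 0.66 for shCtrl replicates 1 to 3 and 0.71, 0.73 and 0.86 for shCAVIN1 replicates 1 to 3, as an estimate that takes these values as single fragments. No interval for counting error can be given, and low values are the least precise.

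An exact 0 in the table can be a failed estimate: the abundant small nuclear RNA RN7SK was listed at 0 in shCtrl replicate 2 and between 106035 and 151555 FPKM in the other 5 libraries. In all, 221 genes were listed at 0 in at least 1 library and at an FPKM of 10 or more in another. Such genes are given as listed at 0, with each library's value. The table also holds 3104 rows for further copies of a gene, of which 6 reached a mean FPKM of 0.5. Genes with near-identical copies or many pseudogenes (HLA class I, RFPL4A and RFPL4AL1, the SNORD116 cluster, histones, ferritin and ribosomal proteins) are uncertain, since fragments may have been split between copies.

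Genes with a mean FPKM over the 6 libraries of at least 0.5 were tested, 13941 in all, on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (linear model with group as the only term, moderated variances with a trend) and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. Log2 fold changes, and the counts of genes changed at least 2-fold or under 1.5-fold, are on the log2(FPKM + 0.5) scale, which understates changes of low genes. Folds written with a gene (such as 2.66-fold) and percentages of control are plain ratios of mean FPKM, which are larger for low genes than the log2 value gives. Errors of fold changes of single genes are standard errors (SE) from limma, and errors of FPKM are standard deviations (SD) over 3 libraries. The SE of the median of a chromosome span comes from the median absolute deviation over its genes, taken as independent. It does not measure the spread between libraries. Before the data were examined, 39 gene lists were fixed from general knowledge of caveolae, prostate stroma, lipid metabolism, inflammation, growth, stress and other cell types, and 930 of their 943 entries matched a row, 18 through an older symbol. The 35 lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists. The test was repeated with a correlation estimated for each list, and fry, which asks whether a list's genes moved to the same side on balance without comparing them with other genes, was run beside it. Counts of list members use the adjustment over all tested genes. Adjusted over the list alone, the counts were the same in 23 lists and differed by at most 3 in the others. The genes named were also set by a rule fixed before the data were examined. They are the caveolae list in full, the 12 largest rises and 12 largest falls among genes past the threshold without overlap between the groups and with a mean FPKM of at least 1 in the higher group, and up to 4 members of each list with the lowest adjusted p (up to 2 by mean FPKM where none passed). The text gives a part of these.

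The design assumed either FPKM or counts, and the FPKM branch applied. Gene positions and types come from GENCODE 29 (GRCh38), to which 23816 symbols matched uniquely, and older symbols were matched through a table of gene names. For the comparison along chromosomes, which was chosen after the data were seen, protein-coding genes with a mean FPKM of at least 2 on the autosomes and X were placed in 10-Mb bins, and bins with at least 10 genes were kept. Spans are runs of at least 2 adjacent bins whose medians all lay 0.25 or more to the same side of 0. A running median over the 30 nearest of these genes in order, the gene itself left out, gave each gene's regional value. Shares of variance between bins are adjusted R squared, with log2 fold changes limited to between -2 and 2. The hairpin sequence was matched to GENCODE 29 transcripts, and its seed match was sought in annotated 3' UTRs.

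In simulated data with the gene means and spreads of this comparison (13941 genes, 200 of them changed), the limma test recovered 79.1% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 97% of those changed 4-fold, and called 18 of 13741 unchanged genes. The changed genes were drawn from those with a mean FPKM of at least 2, so recovery of lower genes was not measured. The noise was normal and independent between genes, and far fewer genes changed than were called in the real data. The alternatives were pseudocounts of 0.1 and 1, no filter on low values and a mean FPKM of at least 2, median-of-ratios scaling, quantile normalization, rescaling to TPM, the replicate number as a block, eBayes without a trend and with robust variances, array weights, and each library left out in turn. Leaving out genes listed at 0, using protein-coding genes alone and subtracting the regional running median were added after the data were seen. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.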

Results

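Expression was profiled by RNA sequencing of total RNA in WPMY-1 cells, which are immortalised stromal cells of the human normal prostate. The question was how lowering CAVIN1, a coat protein of the membrane pits called caveolae, changes gene expression in these cells. There were 6 libraries, 3 of the shCtrl group with the empty vector and 3 of the shCAVIN1 group with a hairpin against CAVIN1. Between 19649 and 20435 genes were above 0 in each library, and between 12422 and 12605 reached an FPKM of 1. Libraries of the same group correlated at Pearson r of 0.921 to 0.94 across genes, and libraries of different groups at 0.896 to 0.913. The first principal component held 36.3% of the variance and the next 19.7%. Values below are mean FPKM ± SD with n = 3 per group unless stated otherwise. Folds and percentages of control given for single genes are ratios of mean FPKM, and log2 fold changes and counts of genes changed at least 2-fold are on the log2(FPKM + 0.5) scale, which understates changes of low genes.

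CAVIN1 was lower in each of the 3 shCAVIN1 libraries than in any shCtrl library. The gene is listed under its older symbol PTRF and lies on chromosome 17 at 42402452 to 42423517 on the minus strand (GRCh38). It stood at 329.6, 346.9 and 330.3 FPKM in shCtrl replicates 1 to 3 and at 133.9, 138.8 and 150.2 FPKM in shCAVIN1 replicates 1 to 3. The mean fell from 336 ± 9.78 to 141 ± 8.33 FPKM, to 42.0% of the control level, with a log2 fold change of -1.25 (SE 0.0586, limma adjusted p = 2.88e-05). An exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow. The hairpin target GTGGAGGTTGAGGAGGTTATT matched the coding sequence of CAVIN1 in exon 2 of 2, at 42405221 to 42405241 on chromosome 17 (transcript ENST00000357037.5).

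Of 12 measured members of the caveolae list, 5 rose, 2 fell (CAVIN1 and PACSIN2) and 5 did not pass the test, with the same counts adjusted over the list alone. The caveolins CAV1 and CAV2, the membrane proteins that form caveolae together with the cavins, rose from 157 ± 8.22 to 187 ± 0.720 FPKM (log2 0.25, SE 0.0510, adjusted p = 0.00655) and from 23.8 ± 3.04 to 35.7 ± 1.30 FPKM (log2 0.58, SE 0.0911, adjusted p = 0.00236). The receptor ROR1 rose 2.66-fold (log2 0.94), from 0.599 ± 0.125 to 1.60 ± 0.124 FPKM, and EHD1 and PACSIN3 rose 1.20-fold and 1.18-fold. PACSIN2, a membrane-bending protein of the caveolar neck, fell from 38.1 ± 1.25 to 27.2 ± 0.356 FPKM. The cavins CAVIN2 (2.25 ± 0.262 and 2.36 ± 0.0578 FPKM), CAVIN3 (5.84 ± 0.708 and 5.53 ± 1.10 FPKM) and CAVIN4 (89% of control, at 0.534 ± 0.0770 FPKM in shCAVIN1) did not pass the test, nor did EHD2 and EHD4, and CAV3 was below the filter. The list as a whole did not differ from other genes (median log2 0.12, camera adjusted p = 0.575). The calls of CAV1, EHD1, PACSIN2 and PACSIN3 were lost when libraries were rescaled to TPM, at log2 fold changes of 0.38, 0.39, -0.36 and 0.35 against 0.25, 0.27, -0.48 and 0.23 in the main test, and EHD1 missed the threshold without shCAVIN1 replicate 3 (adjusted p = 0.0506) and with the replicate number as a block (0.0502).

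**Figure D1:**
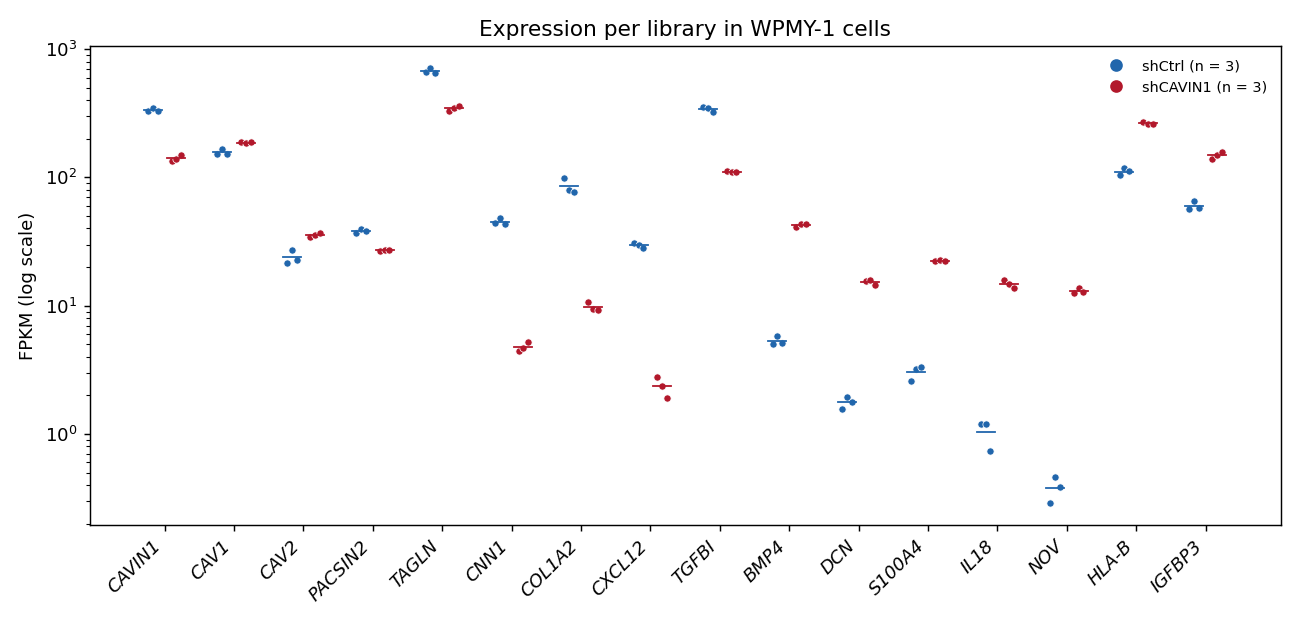
FPKM (log scale) of 16 genes named by the fixed rule in each of the 3 shCtrl libraries (blue) and 3 shCAVIN1 libraries (red), with a line at each group mean. CAVIN1 stood at 336 FPKM on average in shCtrl and 141 in shCAVIN1, and in each gene shown the libraries of the groups did not overlap.

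NOV (also called CCN3), a matricellular protein, rose 34.3-fold (log2 3.95) from 0.381 ± 0.0867 to 13.1 ± 0.680 FPKM. The cytokine IL18 rose 14.1-fold to 14.7 ± 1.03 FPKM, the ligand BMP4 rose 7.99-fold to 42.6 ± 1.38 FPKM, and the collagen-binding proteoglycan DCN rose 8.68-fold to 15.3 ± 0.710 FPKM. Also among the 12 largest rises were the neuropeptide NMU (9.49-fold), the calcium-binding protein S100A4 (7.35-fold), the guidance receptor ROBO1 (10.5-fold), the oxidised LDL receptor OLR1 (8.30-fold), the protease MMP3 (12.6-fold) and the somatostatin receptor SSTR1 (6.90-fold). SPINK6 was at 0.0422 FPKM in shCtrl replicate 1, listed at 0 in the other 2, and at 2.99, 3.34 and 3.40 FPKM in the shCAVIN1 libraries. ANTXRL was listed at 0 in all 3 shCtrl libraries and at 2.02, 2.42 and 2.30 FPKM in the shCAVIN1 libraries. Among protein-coding genes, the BMP antagonist CHRDL1 fell from 56.9 ± 5.78 to 0.642 ± 0.0824 FPKM, and the cytochrome P450 CYP1B1 fell from 33.3 ± 2.76 to 0.312 ± 0.0310 FPKM. ALDH1A2, an enzyme of retinoic acid synthesis, fell from a mean of 13.9 FPKM to 0.0155 ± 0.00598 FPKM, and TMPRSS15 from 14.7 ± 0.844 to 0.00749 ± 0.00737 FPKM. The near-identical copies RFPL4A and RFPL4AL1 also fell, from 33.2 ± 4.19 and 12.7 ± 1.27 FPKM to below 0.11 FPKM in each shCAVIN1 library, and are uncertain as single genes. The other 6 of the 12 largest falls were short RNAs. SNORD83B, SNORD116-20 and SNORD88A were listed at 0 in all 3 shCAVIN1 libraries and at means of 247, 98.4 and 80.3 FPKM in shCtrl. SNORD116-18, MIR630 and SNORD116-16 were listed at 0 in 2 shCAVIN1 libraries and at 71.4, 82.9 and 69.4 FPKM in the remaining library. These last 3 calls were lost when any shCtrl library was left out, without 2 of the shCAVIN1 libraries, with no filter on low values and with robust variances, and that of SNORD116-16 also with the regional median subtracted, at log2 fold changes that stayed between -6.82 and -4.83.

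In all, 7734 of 13941 tested genes (55.5%) changed, 3807 higher and 3927 lower in shCAVIN1. Most changes were small: 5224 of these genes changed by under 1.5-fold, and the median absolute log2 fold change of changed genes was 0.44. Only 772 changed at least 2-fold, 369 higher and 403 lower. The libraries of the groups did not overlap for 9006 genes (64.6%), where chance gives 10% for 3 against 3. After rescaling to TPM, 3496 genes changed and 64.5% of them were higher, against 49.2% in the main test, with the median over tested genes moving from -0.02 to 0.09 on the log2 scale. With a filter at a mean FPKM of 2, 500 genes changed at least 2-fold. Among genes changed at least 2-fold, 47.8% were higher in the main test. The balance turned under 2 scalings, to 59.1% of 900 genes after rescaling to TPM and 53.2% of 771 after quantile normalization. Under the other alternatives the lower genes stayed more numerous.

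Of 29 measured interferon-stimulated genes, 19 rose and 3 fell (adjusted over the list alone, 19 and 4), with a median log2 fold change of 0.50. The list passed camera (adjusted p = 0.00167) but not with an estimated correlation (adjusted p = 0.707 with an estimated correlation), nor with a mean FPKM filter of 2 (median 0.43, adjusted p = 0.0653). The antiviral GTPase MX1 rose from 0.483 ± 0.0121 to 2.01 ± 0.133 FPKM, DDX60 from 1.48 ± 0.0578 to 3.29 ± 0.118 FPKM, and the ubiquitin ligase HERC5 from 0.264 ± 0.0320 to 1.41 ± 0.110 FPKM, all at low levels. The 3 members that fell were the transcription factors STAT2, IRF7 and IRF9, named after their values were seen. In the antigen presentation list, 12 of 16 members rose and 1 fell, ERAP2 (13 and 1 adjusted over the list alone), with camera adjusted p = 0.0018, against adjusted p = 0.707 with an estimated correlation. HLA-B, a class I molecule, rose from 111 ± 7.02 to 264 ± 3.85 FPKM, HLA-C from 94.6 ± 6.25 to 184 ± 6.04 FPKM, and the immunoproteasome subunit PSMB9 from 6.88 ± 0.303 to 16.7 ± 0.796 FPKM. The HLA values are uncertain between class I copies. In the NF-kB response list, 15 of 22 members rose and 1 fell, with the same counts adjusted over the list alone and camera adjusted p = 0.0018, against adjusted p = 0.707 with an estimated correlation. TNFAIP2 rose 2.98-fold to 41.6 ± 1.59 FPKM, the pattern recognition molecule PTX3 rose 2.35-fold to 14.8 ± 1.08 FPKM, and NFKB1, a subunit of NF-kB itself, rose 1.46-fold. Cytokines and chemokines went both ways (4 of 10 rose, 2 fell): the chemokine CXCL12 fell from 29.7 ± 1.37 to 2.36 ± 0.438 FPKM and LIF to 62.1% of its control level, and CSF1 and IL32 rose 2.36-fold (log2 1.08) and 4.13-fold (log2 1.35), with camera adjusted p = 0.571 for the list.

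Of 32 measured collagens and matrix genes, 10 rose and 16 fell (11 and 16 adjusted over the list alone), 4 of the rises and 8 of the falls by at least 2-fold. The type I collagen chain COL1A2 fell from 85.5 ± 11.9 to 9.78 ± 0.731 FPKM and the matricellular protein POSTN from 8.24 ± 0.360 to 1.61 ± 0.0425 FPKM, and COL8A1 rose from 12.8 ± 0.166 to 35.1 ± 0.666 FPKM. Among contractile genes, 8 of 18 rose and 7 fell (8 and 9 adjusted over the list alone). Calponin (CNN1) fell from 45.3 ± 2.47 to 4.79 ± 0.417 FPKM and transgelin (TAGLN) from 675 ± 33.3 to 346 ± 12.7 FPKM, and smooth muscle actin (ACTA2) rose from 4.94 ± 0.289 to 9.89 ± 0.287 FPKM and MYLK 1.77-fold. Among 10 measured fibroblast markers, 5 rose and 2 fell: the adhesion molecule CDH11 fell from 7.42 ± 0.288 to 0.0296 ± 0.0108 FPKM, and the transcription factor TWIST1 rose from 6.74 ± 0.494 to 23.1 ± 3.41 FPKM. In the TGF-beta response list, 5 of 23 members rose and 11 fell. TGFBI, a matrix protein induced by TGF-beta, fell from 342 ± 18.5 to 111 ± 0.934 FPKM and the receptor TGFBR1 to 39.5% of control, and SMAD6 and ID3, which respond to BMP signals, rose 2.80-fold and 2.23-fold. Matrix proteases and inhibitors (10 of 25 rose, 8 fell) included MMP2, which fell from 10.3 ± 0.519 to 3.40 ± 0.0938 FPKM, beside the rise of MMP3. Integrins and focal adhesion genes (3 of 25 rose, 11 fell) included ITGAV, lower at 61.9% of control, and LPXN, 3.38-fold higher. None of these 6 lists passed camera, with adjusted p of 0.434 (matrix), 0.943 (contractile), 0.245 (fibroblast), 0.167 (TGF-beta), 0.877 (proteases) and 0.167 (integrins). By fry, which does not compare with other genes, 5 of them passed, with adjusted p of 0.0246 (contractile), 0.00764 (fibroblast), 0.00124 (TGF-beta), 0.0113 (proteases) and 0.0101 (integrins), and the matrix list did not (0.0571). Fry called the fibroblast list lower, although its median (0.38) and camera direction were positive. For proteases the median was negative (-0.04) but the mean and the camera direction positive, and the median turned positive under quantile normalization and TPM. The contractile median (-0.07) turned positive under TPM, which also moved the median of all tested genes from -0.02 to 0.09.

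Targets of YAP and TAZ, the transcriptional coactivators of the Hippo pathway, rose in 14 of 22 cases and fell in 3, with the same counts adjusted over the list alone. IGFBP3 rose from 59.9 ± 4.73 to 149 ± 9.16 FPKM, NT5E from 2.57 ± 0.166 to 5.22 ± 0.187 FPKM and WWC1 1.82-fold, and TGFB2 fell from 23.2 ± 1.11 to 11.9 ± 0.833 FPKM. The camera adjusted p was 0.0225 at a median of 0.25, against adjusted p = 0.707 with an estimated correlation. The call was lost under quantile normalization (median 0.27, adjusted p = 0.0804) and TPM (median 0.37, adjusted p = 0.0891).

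Genes of lipid metabolism rose and fell within the same pathways. In cholesterol synthesis and uptake, 8 of 25 members rose and 13 fell (8 and 14 adjusted over the list alone). HMGCS1, the HMG-CoA synthase of the cytosol, fell to 48.9% of control, from 24.5 ± 1.35 FPKM, and the kinase PMVK rose 2.37-fold. In fatty acid synthesis, 9 of 17 members rose and 1 fell (9 and 2 adjusted over the list alone), among them the lipogenic transcription factor SREBF1 (1.98-fold higher, at 24.9 ± 0.497 FPKM), SCD5 and ELOVL6 (1.86-fold each). CPT1A, which admits fatty acids to the mitochondrion, rose from 2.31 ± 0.111 to 6.02 ± 0.423 FPKM in a fatty acid oxidation list with 8 of 19 members higher and 4 lower. Lipid droplet genes (7 of 19 rose and 7 fell, 8 and 7 adjusted over the list alone) included DGAT2, 2.88-fold higher. In cholesterol efflux (5 of 12 rose and 3 fell, 6 and 3 adjusted over the list alone), the transporter ABCA1 fell to 39.4% of control and APOE rose 1.38-fold. In steroid synthesis (6 of 13 rose, 1 fell), SRD5A1, the type 1 steroid 5-alpha-reductase, fell from 10.2 ± 0.423 to 4.01 ± 0.396 FPKM, and of 9 androgen receptor targets 4 rose, ELL2 among them (1.53-fold), and 2 fell. Insulin and IGF signalling genes (9 of 19 rose, 7 fell) included IGFBP7, 2.45-fold higher, and IRS1, lower at 60.9% of control. Camera passed none of these lists, with adjusted p of 0.0627 for fatty acid synthesis, 0.167 for fatty acid oxidation, 0.434 for efflux and 0.571 for the other 5. Fatty acid synthesis passed without shCtrl replicate 1 (adjusted p = 0.0287) and without shCAVIN1 replicate 3 (0.0471), against adjusted p = 0.707 with an estimated correlation over all libraries. For the steroid, androgen and insulin lists the median was negative (-0.02, -0.01 and -0.07) but the mean and camera direction positive, and each of these medians turned positive under TPM, where the shift of all tested genes is of about the same size. The androgen median also turned positive under median-of-ratios scaling and the steroid median under quantile normalization, and these scalings moved the median of all tested genes from -0.02 to -0.01 and to 0.01.

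Of 31 genes of the G2 and M phases, 15 rose, 0 fell and 16 did not pass (the same adjusted over the list alone), with camera adjusted p = 0.003, against adjusted p = 0.844 with an estimated correlation. Those that rose included the spindle checkpoint kinase BUB1 (36.9 ± 2.91 to 61.4 ± 0.512 FPKM) and CDC20 (81.3 ± 4.54 to 129 ± 4.44 FPKM). The S phase list split evenly, with 9 of 34 higher and 11 lower (camera adjusted p = 0.843), and its median of 0.01 turned negative under quantile normalization. Of 24 p53 targets, 16 rose and 2 fell (the same adjusted over the list alone), with camera adjusted p = 0.00238, against adjusted p = 0.707 with an estimated correlation. The death receptor FAS rose from 1.71 ± 0.0463 to 3.56 ± 0.0277 FPKM and the stress cytokine GDF15 from 4.03 ± 0.452 to 10.4 ± 0.504 FPKM. Of 51 ribosomal protein genes, 2 rose, 20 fell and 29 did not pass (2 and 17 past it adjusted over the list alone). Their median log2 fold change was -0.17, with camera adjusted p = 0.0225, against adjusted p = 0.844 with an estimated correlation. RPL4 fell from 1758 ± 159 to 1076 ± 17.5 FPKM. In the RNA polymerase I and ribosome biogenesis list, of interest because CAVIN1 is also known as a release factor of that polymerase, 6 of 36 members rose and 15 fell. POLR1E rose 1.64-fold and the transcription factor MYC fell from 66.3 ± 8.20 to 41.8 ± 2.66 FPKM, in a list that did not pass camera (adjusted p = 0.349). The ribosomal call was lost under quantile normalization (median -0.07, adjusted p = 0.288), TPM (median -0.05, 0.163), without shCtrl replicate 2 (0.0594), without shCAVIN1 replicate 1 (0.0552), with the replicate number as a block (0.0515) and by fry (0.0569). The calls of RPL4 and MYC were lost under TPM, at log2 fold changes of -0.58 and -0.53 against -0.70 and -0.65.

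Stress and energy genes moved in both directions. The chaperone HYOU1 fell from 99.2 ± 2.19 to 52.0 ± 2.11 FPKM in the unfolded protein response list (3 of 27 rose, 11 fell). In hypoxia and glycolysis (7 of 30 rose and 13 fell, 8 and 13 adjusted over the list alone), PDK1 fell to 48.2% and CA12 to 33.5% of control, and the lactate transporter SLC16A3 rose 1.70-fold. Of 41 nuclear genes of oxidative phosphorylation, 16 rose and 9 fell, with NDUFV1 at 54.2% of control and ATP5MC1 1.75-fold higher. The glutathione synthesis subunit GCLM rose 2.12-fold among NRF2 targets (6 of 16 rose, 2 fell). In lysosome and autophagy genes (11 of 25 rose and 8 fell, 11 and 9 adjusted over the list alone), the transcription factor TFE3 rose from 12.3 ± 0.464 to 29.8 ± 0.492 FPKM and the receptor SQSTM1 from 63.3 ± 2.08 to 145 ± 2.39 FPKM. Heat shock proteins (4 of 14 rose, 2 fell), immediate early genes (4 of 15 rose and 4 fell, 5 and 4 adjusted over the list alone, with KLF2 3.02-fold higher) and replication-dependent histones (2 of 15 rose, 0 fell) completed these lists. Camera passed none of them, with adjusted p of 0.22 for the unfolded protein response, 0.479 for hypoxia, 0.571 for oxidative phosphorylation, 0.167 for NRF2, 0.515 for lysosome, 0.515 for heat shock, 0.575 for immediate early genes and 0.571 for histones. The hypoxia median (-0.11) turned positive under TPM (0.01), by about the shift of all tested genes, and the lysosome median (0.01) negative under quantile normalization.

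Most immune, endothelial and neural markers were below the filter. Of 8 measured epithelial markers, 2 rose and 4 fell (camera adjusted p = 0.571), with KRT18 lower at 219 ± 7.60 against 385 ± 17.7 FPKM. Of 18 immune markers only CD68, which rose from 6.44 ± 0.469 to 9.25 ± 0.278 FPKM, and CD14, which fell from 1.22 ± 0.184 to 0.508 ± 0.0964 FPKM, passed the filter on low values. The endothelial markers TEK and FLT1 rose to 0.941 ± 0.0177 and 0.770 ± 0.0232 FPKM. Of 3 measured neural markers, MAP2 rose to 1.29 ± 0.0440 FPKM and ENO2 1.15-fold. These last 3 lists had too few measured genes for a test, and mitochondrially encoded genes were not analysed here. Among 10 nuclear and structural noncoding RNAs 1 rose (MEG3, 1.34-fold) and 2 fell (GAS5 and SNHG1, to 59.4% and 71.6% of control), with camera adjusted p = 0.571, in a list where RN7SK and RN7SL2 were listed at 0 in some libraries. The calls of GAS5, SNHG1 and ENO2 were lost under TPM (log2 -0.62, -0.35 and 0.32), SNHG1 also with the regional median subtracted, and ENO2 in 7 alternatives in all.

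**Figure D2:**
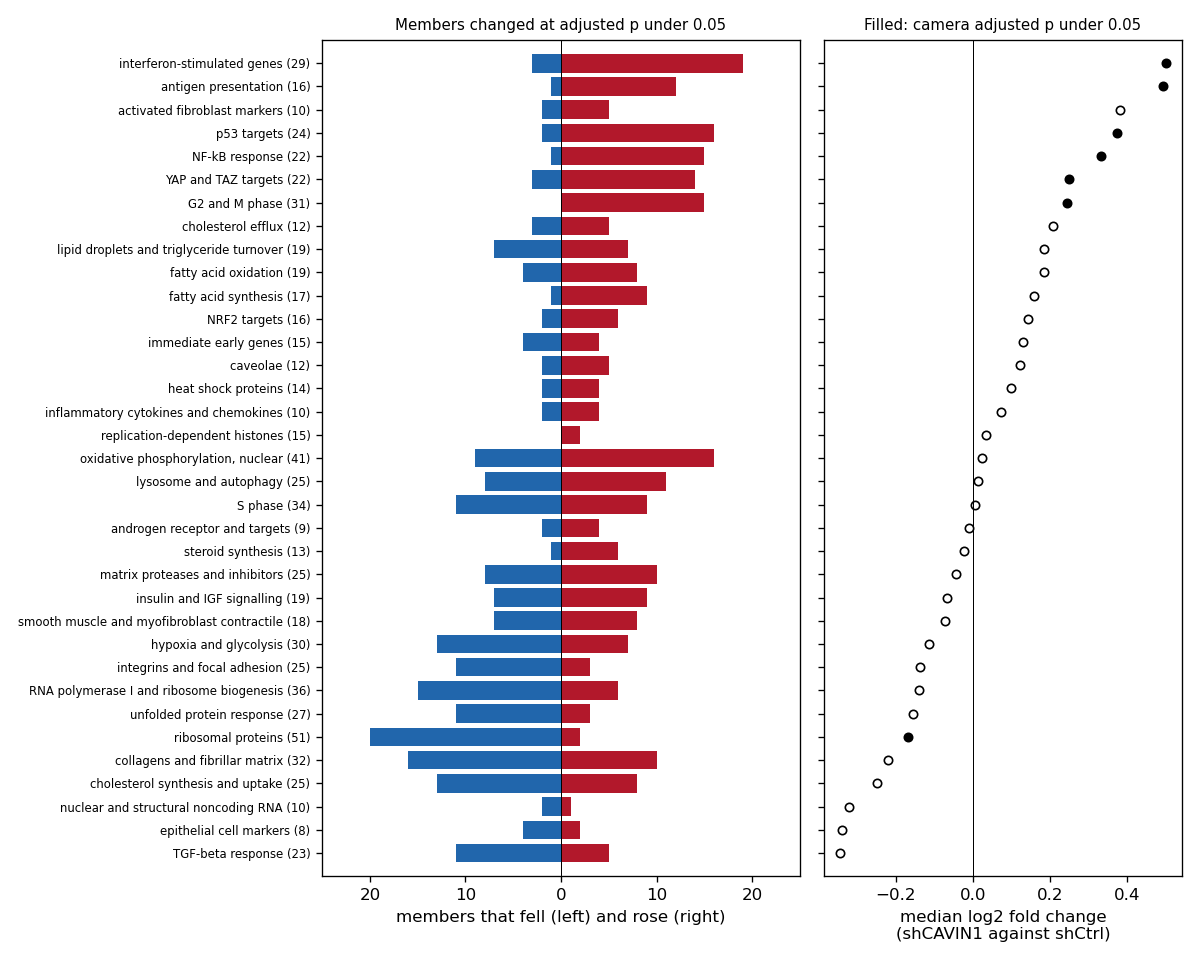
Left, number of members of each of the 35 tested gene lists that fell (blue) or rose (red) in shCAVIN1 at a limma adjusted p under 0.05, with the number measured in brackets. Right, median log2 fold change of each list, filled where camera with the preset correlation passed: 6 lists were higher and 1, ribosomal proteins, was lower.

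Across the 35 lists, 7 passed camera with the preset correlation, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.707. By fry, 25 lists passed, and fry's mixed test, which asks for change in either direction, passed all 35.

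Fold changes also differed by chromosome region, a comparison chosen after the data were seen. Of 10273 protein-coding genes with a position, those in the 277 bins of 10 Mb with at least 10 genes were compared, and 24.2% of the variance of their log2 fold changes lay between bins, against at most 0.93% in 10000 shuffles of gene positions (permutation p = 1e-04, the smallest these shuffles can give, with genes not independent replicates). There were 15 spans, 9 higher and 6 lower in shCAVIN1, holding 2105 genes (20.5% of the 10273). This share is not the full extent of the shifts, since single bins and medians nearer to 0 are left out. Examples of such bins are chromosome 11 from 0 to 10 Mb (80 genes, median -0.485) and chromosome 17 from 80 to 90 Mb (54 genes, 0.539). On chromosome 2 from 150468195 to 241768816 (GRCh38), 89.7% of 263 genes were lower, with a median log2 fold change of -0.41 (SE 0.0230); 196 of them fell and 14 rose. On chromosome 11 from 57299638 to 119729084, 86.8% of 380 genes were lower (median -0.38, SE 0.0213), and on chromosome 20 from 10401009 to 64287821, 88.9% of 234 genes (median -0.36, SE 0.0232). On chromosome 5 from 31400497 to 98928957, which holds HMGCS1, 90.2% of 163 genes were lower (median -0.41, SE 0.0340). On chromosome 13 from 93226842 to 114337626, 98% of 49 genes were higher (median 0.64, SE 0.0597), on chromosome 10 from 42574185 to 59906656, 97.1% of 34 genes (median 0.68, SE 0.0375), and on chromosome 1 from 144421386 to 170085208, which holds S100A4 and PMVK, 76.2% of 202 genes (median 0.42, SE 0.0351). The 3 shCAVIN1 libraries gave nearly the same medians in each span, for example -0.41 to -0.40 on chromosome 2 and 0.62 to 0.65 on chromosome 13. The shCtrl libraries lay between -0.06 and 0.10 in all 15 spans. All values are differences from the shCtrl mean, so this range gives the spread of the shCtrl libraries and not which group was shifted. Of 1651 changed genes in the spans, 1523 changed in the direction of their span. Spans were chosen by the bin medians of these same values, so this count and the shares of genes above follow largely from the choice. The running median at CAVIN1 itself was close to 0 (-1.05e-05). At some genes named above it lay to the side of their own log2 fold change: -0.571 at TAGLN (-0.96), -0.535 at HYOU1 (-0.925), -0.426 at ITGAV (-0.676), 0.539 at SLC16A3 (0.766) and 0.62 at TFE3 (1.245). At others it lay to the opposite side, such as -0.596 at DGAT2 (1.06), -0.361 at LPXN (1.55) and -0.353 at CPT1A (1.21). These examples were picked after their values were seen. With each gene's running median subtracted, 6419 genes changed, 5227 of them in common with the main test, PACSIN3 was no longer called (log2 0.00), CAVIN2 was called higher (log2 0.39) and CAVIN3 became higher (log2 0.53, adjusted p = 0.03). The subtracted medians were treated as known, so the tests after subtraction carry none of their error. At CAVIN3 the running median was -0.612 and the main log2 fold change -0.08, so its call came mostly from the subtraction. With the subtraction, the lists past camera numbered 10, with fatty acid synthesis (adjusted p = 0.00296) and NRF2 targets (0.0181) higher and the unfolded protein response (0.038) lower beside the 7 of the main test. Without the subtraction these 3 lists had adjusted p = 0.707, 0.844 and 0.844 with an estimated correlation. Medians nearer to 0 after the subtraction included those of integrins (-0.14 to -0.05), the TGF-beta response (-0.34 to -0.11), RNA polymerase I (-0.14 to -0.02), hypoxia (-0.11 to -0.02), epithelial markers (-0.34 to -0.07), lipid droplets (0.19 to 0.01) and cholesterol efflux (0.21 to 0.13). Medians further from 0 included those of fibroblast markers (0.38 to 0.59), caveolae (0.12 to 0.26), fatty acid synthesis (0.16 to 0.31), collagens (-0.22 to -0.27) and lysosome (0.01 to 0.13), and medians that changed sign those of insulin signalling (-0.07 to 0.21), steroid synthesis (-0.02 to 0.05), androgen targets (-0.01 to 0.08), noncoding RNA (-0.32 to 0.02), immediate early genes (0.13 to -0.01) and heat shock proteins (0.10 to -0.02).

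**Figure D3:**
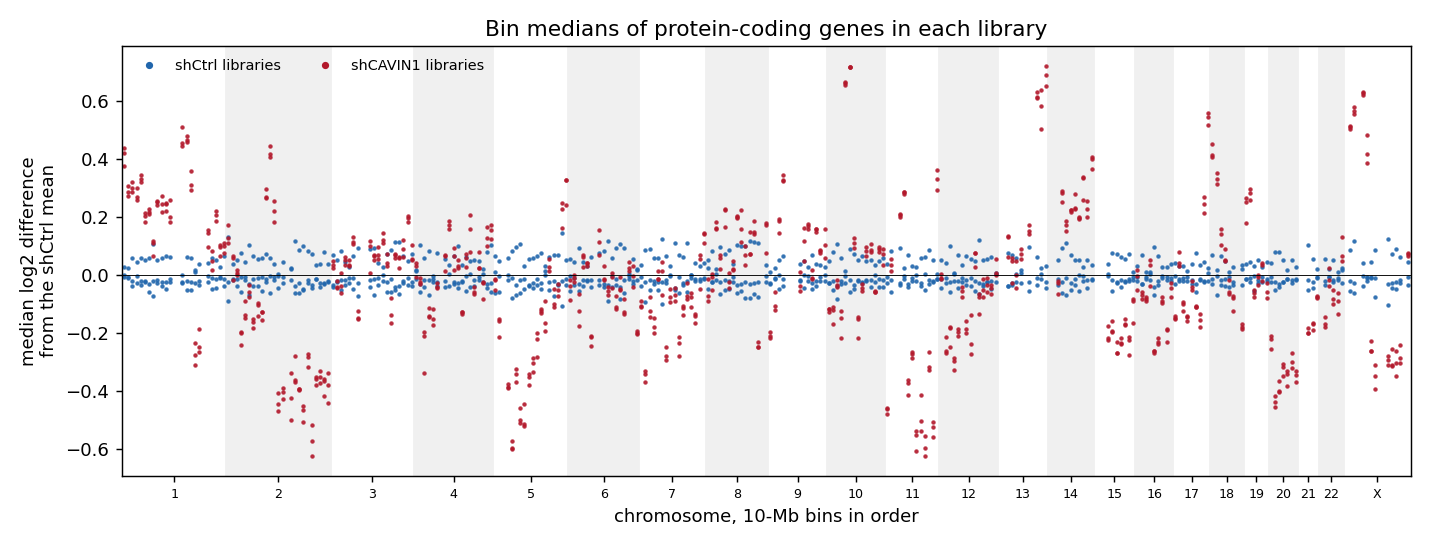
Median log2 difference from the shCtrl mean for protein-coding genes in 10-Mb bins along chromosomes 1 to 22 and X, in each of the 3 shCtrl libraries (blue) and 3 shCAVIN1 libraries (red). The shCAVIN1 libraries depart together from 0 in blocks, such as the end of the long arm of chromosome 2 (-0.41) and of chromosome 13 (0.64). The shCtrl libraries lie near 0 because their own mean is the reference, so the plot does not show which group was shifted.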

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

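The fall of CAVIN1 passed the threshold under all 20 alternatives, with log2 fold changes of -1.30 to -1.13 (-1.30 to -1.21 with a library left out). The number of genes changed (7734) fell to 3496 after rescaling to TPM, where RN7SK and a few other rows decide the sums, and lay between 6218 and 8468 with a library left out; leaving out genes listed at 0 gave 7977 and array weights gave 10912. The number changed at least 2-fold (772) fell to 500 with a mean FPKM of at least 2, where fewer genes were tested, and lay between 764 and 835 with a library left out. It followed the pseudocount, at 1086 with 0.1 and 534 with 1, and was 928 with array weights. The number of lists changed (7) became 0 with an estimated correlation and 25 with fry, which asks another question, and lay between 6 and 8 with a library left out. Fry also turned the activated fibroblast list (median 0.38 under either test) from higher to lower. Subtracting the regional running median, chosen after the data were seen, gave 10 lists. It changed the sign of CAVIN3 (0.53), ABCC4 (-0.15), PLPP1 (0.12), POLA1 (-0.0343), DNAJC3 (-0.0362), NDUFS1 (0.0427) and HIST2H2BE (-0.0310), by construction through the value of their neighbours. Only CAVIN3 and PLPP1 passed the threshold afterwards (limma adjusted p = 0.03 and 0.0434), and CAVIN3 had not passed in the main test. These p-values leave out the error of the subtracted medians. Among single genes named by the rule, 72 of the results under alternatives lost the threshold with the same sign and 1 gained it. The 7 above changed sign with the threshold passed in the main test or the alternative. The other 3224 kept their side of the threshold, and changes of sign that passed in neither test are counted among them. Replicate numbers did not pair the libraries: the deviations of same-numbered libraries correlated at 0.094, 0.071 and -0.028, and 3 of 6 libraries correlated best with their own number. With the replicate number as a block, 7167 genes changed, 778 by at least 2-fold, and 6 lists, without ribosomal proteins (adjusted p = 0.0515). The cause was not tested where none is given. The planned count models were not run, since whole fragments were not recovered. Absolute depth is unknown and limits what low values can show.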

Other observations

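All tests in this part except the splits of the samples address patterns first seen in these data. The bounds for the tests on failed estimates and on immune cells were set after the values they use were seen, and the genes named in the next paragraphs were picked after their values were seen unless the rule named them.

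Beyond the genes already described, several abundant matrix and adhesion genes fell. Fibronectin (FN1) fell from 199 FPKM to 57.8 FPKM on average (log2 -1.74, adjusted p = 0.000792), tenascin C (TNC) from 52.1 to 12.7 FPKM (-1.96, 0.000357), the crosslinking enzyme LOX from 31.5 to 10.9 FPKM (-1.48, 0.000353) and COL3A1 from 17.9 to 6.72 FPKM (-1.35, 4.83e-05). Fibulin 1 (FBLN1) rose from 7.09 to 21.5 FPKM (1.53, 8.18e-05). Within the TGF-beta response list, the activin subunit INHBA fell from 2.90 FPKM (log2 -1.14, adjusted p = 0.00012), and the BMP-responsive ID1 rose from 77.4 to 115 FPKM (0.57, 0.00439), beside the rises of ID3, SMAD6 and the ligand BMP4 and the fall of the BMP antagonist CHRDL1. The BMP and TGF-beta genes were not tested as separate sets.

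With 10 possible splits of 3 against 3, no share of splits under 0.05 can be reached. The real split gave 7734 changed genes, and the highest of the other splits gave 6, so 1 of the 10 splits reached the real count. For genes changed at least 2-fold the values were 772 and 6, again 1 of 10. For gene lists changed the real split gave 7 and the highest other 8, and 3 of the 10 splits gave at least 7.

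The blocks of shifted expression along chromosomes are a pattern that a reader of the list results would want to follow up. The real split put 24.2% of the variance between bins and the highest other split 20.1% (1 of 10 reached the real value), where the other splits still carry a part of the group difference because they mix the groups 2 to 1; a library set against the others of its own group gave between -0.39% and 3.65%. A fit on transcript GC content, length and expression left 101% of the share in place, which argues against such a bias, and log2 fold changes correlated across genes with the median of genes 3 to 10 Mb away at Pearson r of 0.418 (Spearman rho 0.467, at most 0.0295 in 1000 shuffles of positions), which argues against clusters of adjacent co-regulated genes. Bin medians of the lower-expressed genes followed those of the higher-expressed genes with a slope of 0.799 (95% interval 0.721 to 0.876). Gene dosage would give such a slope, but so would any other cause that shifts the genes of a region alike, so the slope does not separate them. A candidate explanation is a difference in gene dosage, that is in chromosome copy number, between the shCtrl and shCAVIN1 cell populations. This hypothesis was found and tested on the same values. Whether such a difference would come with the knockdown or with the cells that founded each selected population was not tested, and DNA was not analysed here.

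A further pattern is genes that were expressed in shCtrl and near 0 in shCAVIN1. There were 24 genes with at least 2 FPKM in all shCtrl libraries and at most 0.1 FPKM in all shCAVIN1 libraries, against 2 in the other direction; 19 of the 24 were protein-coding, among them TMPRSS15, ALDH1A2, CDH11, FGF13, CNTN1, TIAM1, SGCD, PTPRD, CADM1, NKX2-1 and EPDR1. Their nearest neighbours were taken within 2 Mb among protein-coding genes with a mean FPKM of at least 2 over all libraries, with the 24 genes left out. These 38 neighbours had a median log2 fold change of -0.178 (quartiles -0.473 and 0.0399), which argues against deletions that reach them for most of these genes. Neighbours of low expression, or themselves near 0 in shCAVIN1, could be missed by this choice, so deletions limited to such genes were not addressed. The median does not settle single genes: 2 neighbours lay below -1, and the neighbour medians were -2.89 for RFPL4AL1 (with its near-identical copy RFPL4A as 1 neighbour) and -1.45 for CLSTN2. Of the 19, 15.8% were listed at exactly 0 in all 3 shCAVIN1 libraries, which argues against failed estimates as the whole cause. The share with a seed match of the hairpin (AGGTTAT) in a 3' UTR lay 10.9 percentage points below that of all genes (difference -10.9, with 0 of 17 searched), which argues against seed-mediated silencing. Silencing or loss restricted to single genes in the founding cells, or a response to the knockdown, may account for them, and neither was tested.

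The interferon, antigen presentation and NF-kB lists were higher by camera with the preset correlation. None of the 3 passed with an estimated correlation (adjusted p = 0.707 for each). These lists were set against the same regional shifts and against immune cells in the cultures. After each gene's regional running median was subtracted, the pooled median of the 67 genes went from 0.465 to 0.503, 108% of its value, which argues against the regional shifts as the source. Of 18 immune markers, 1 (CD68, also expressed in shCtrl) reached a mean FPKM of 1 in the shCAVIN1 libraries, and PTPRC stood at 0.135 FPKM, which argues against immune cells in the cultures. A response to the knockdown, to the hairpin RNA or to viral transduction beyond that of the empty vector, and a difference between founding populations stay open, and each of these was not tested.

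Over all 11851 genes with a searched 3' UTR, the 1297 genes with the seed match had a median log2 fold change 0.026 lower than the others after removal of UTR length (difference -0.026), at percentile 23.9 among 209 other 7-mers of the same base content.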
